A study of Mus musculus with 2 samples.

How the data were processed

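Total RNA from 2 pools of 40 embryos each, 1 at E10.5 and 1 at E11.5, was labelled with Cy3 and hybridised to 1-colour Agilent miRNA arrays, per the labels' protocols. The deposited scanner files give an intensity per spot, background-subtracted and spatially detrended, per the file headers, and not normalized between arrays. The headers name Feature Extraction 10.7.1.1, design 031184 and build mm9, while the submitters' processing notes name Feature Extraction 9.5.1.1. The deposited value table holds intensity on a linear scale, 1 value per miRNA. From its values, both columns have the same highest value (3256), its ranks follow the total gene signal (Spearman's rho 0.992 and 0.997 across miRNAs), and 0.1 stands for each miRNA that Feature Extraction did not call detected. Its column medians are 0.1 and 0.1 over all miRNAs, and 45.0 and 26.6 above that value. How the authors normalized the table is not stated in the labels, and it served as an alternative here.

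Spots with an outlier flag (2058 of 43200 miRNA spots at E10.5 and 2118 at E11.5) were left out, and the processed intensities of the other spots were averaged per probe. A probe counted as detected where at least 50% of its spots were well above background. Each array was divided by its 75th percentile over the probes detected on both arrays (194 at E10.5 and 482 at E11.5) and log2 was taken. A miRNA's value is the mean over its probes detected on both arrays of log2 E11.5 minus log2 E10.5. Over 1 probe was used for 80 miRNAs, of which 3 had probes in both directions. The median spot SE was 0.031, and negative controls averaged 7.87 ± 6.16 and 5.88 ± 5.60 (SD over 1000 spots each). The number of arrays limits the precision.

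The comparison of the 2 stages had no test. Counts used a 2-fold threshold. Lists of miRNAs, and the clusters, were chosen before the data were examined, and covered myogenic, myoblast-linked, let-7, miR-125 and miR-99, Mir17, pluripotency, neural, epithelial, sensory epithelium, erythroid, leukocyte, endothelial, mesenchymal, cartilage, Hox cluster, Dlk1-Dio3, miR-15 and miR-16, miR-29, miR-30, miR-34 and miR-449, Sfmbt2 intron and viral miRNAs. A list with at least 3 measured members has a median, with its percentile among 10000 random lists, each member replaced by 1 of the 40 miRNAs nearest in brightness. Members of one transcript are not independent, which these random lists do not copy. The text names, among miRNAs whose probes share a direction and whose difference exceeds 2 spot SEs, the 12 highest and 12 lowest differences, the 5 largest bounds per stage, every myogenic miRNA, and the highest and lowest measured member of each other list. Other names were chosen after their values were seen. They are miR-335-5p, miR-203, miR-223, let-7b, miR-98, miR-125a, miR-429, miR-3107 and mcmv-miR-m01-2.

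Names and mm9 positions are those of the scanner files, with a version suffix removed from 9 names. Neighbouring and host genes come from a GRCm38.p6 gene table, from which no position was taken. Control probes were not used in the comparison. Viral miRNAs were counted with the others, 1 of those detected at E10.5 only and 1 of those at E11.5 only. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

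The steps were tested on simulated data made from the E10.5 probe means and spot SDs with a gain of 2.49. Of 168 simulated miRNAs, 15 of 15 that were 3-fold higher and 15 of 15 that were 3-fold lower were called, with 0 of 30 changed by 1.5-fold and 0 of 108 unchanged. The scaling moved all values by -0.21 there. Both simulated arrays came from the same probe means, with spot noise and 1 common gain only. These calls thus check the steps and say nothing on noise between arrays or on unequal gains. Alternatives covered the scaling (75th percentile of all probes, median, quantile, none, spike-ins, control probes), normexp background correction with an offset of 50, the brightest probe, the total gene signal, other detection rules, filters on dim miRNAs, outlier spots and the value table.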

Results

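MicroRNA levels were measured in the mouse tongue primordium, the medial region of the mandibular arch of ICR embryos, at embryonic day E10.5 and at E11.5. Per the series description, myoblast differentiation begins in this window as muscle regulatory genes become active. RNA from 40 embryos was pooled per stage and hybridised to 1 array per stage, so there are no replicates, no difference was tested, and every value describes these 2 arrays. The errors given are standard errors (SE) over the repeated spots of a probe and hold spot noise within an array only. Each array carried 2780 probes for 1080 miRNAs. At E10.5, 144 miRNAs (13.3%) were detected, and at E11.5 there were 199 (18.4%). No miRNA spot was saturated. Over the 218 probes detected on both arrays, unscaled intensity was higher at E11.5 by a median log2 ratio of 1.20, and scaling to the 75th percentile of these probes took 1.31 off every log2 difference. All differences below are scaled ones, E11.5 minus E10.5, and describe abundance relative to the other detected miRNAs. Their median over miRNAs was -0.07.

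The first question was whether the miRNAs of striated muscle appear between the stages. Of 18 myogenic miRNAs on the array, 0 were detected at E10.5 and 4 at E11.5: miR-206, miR-133b, miR-1a and miR-133a. With detection by every spot 3 remained, without miR-133a. The brighter probe of miR-206, a miRNA of skeletal muscle induced by myogenic regulatory factors, had an intensity of 284 ± 18.1 (SD over 20 spots) at E11.5 and -1.87 ± 5.92 at E10.5. The other miR-206 probe gave 135 ± 6.67 against -4.04 ± 2.94. The probes of miR-133b gave 220 and 84.3 at E11.5 against 7.96 and 6.32 at E10.5. miR-206 and miR-133b are neighbours on chromosome 1 (mm9; probe targets 20669143 to 20669157 and 20672919 to 20672936), and both lie within the span of the noncoding RNA gene Lincmd1 in the GRCm38.p6 gene table.

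For a miRNA not well above background at one stage, the fold is a lower bound, taken against the higher of that array's lowest detected probe and the probe's own intensity there, after scaling. On this basis miR-206 was at least 2.55-fold higher at E11.5, miR-133b at least 1.77-fold and miR-1a at least 1.71-fold. Without scaling these bounds were 6.33, 4.40 and 4.26, while with normexp background correction the log2 bound was 0.35 for miR-206 and at the limit of 0 for miR-133b (0.0016), and miR-1a had no bound above 1. For miR-1a, 1 probe was detected (132 at E11.5, 5.61 at E10.5) and the other was not well above background at either stage (13.3 and -1.59). For miR-133a, 1 probe reached 35.6 at E11.5 against 5.91 at E10.5, and its other probe was not well above background. It had no bound above 1 as scaled and one of 1.15-fold without scaling. Its bound was also above 1 with the 75th percentile of all probes, the total gene signal and the gene detection flag. The other 14 myogenic miRNAs on the array were not well above background at either stage: the cardiac pair miR-208a (miR-208a-3p, miR-208a-5p) and miR-208b (with miR-208b*), miR-499 and miR-499*, miR-1b-3p, miR-1b-5p, miR-486*, and the passenger strands miR-206*, miR-133a*, miR-133b*, miR-1a-1* and miR-1a-2*. The other arm of miR-486 was not on the array under that name. Whether a probe of another name reads it was not examined. miR-3107, whose gene neighbours Mir486 in the GRCm38.p6 gene table, was detected at E11.5 only (55.1, against 4.39 at E10.5). It had no bound above 1 as scaled, and one of 1.78-fold without scaling.

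**Figure D1:**
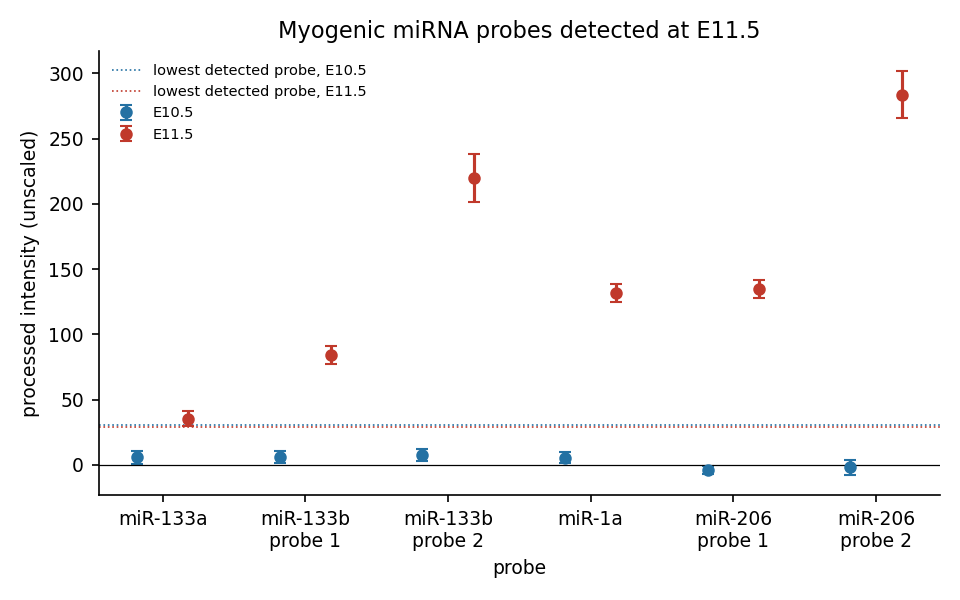
Unscaled processed intensity (vertical axis) of each myogenic miRNA probe detected at E11.5, at E10.5 (blue) and E11.5 (red). Points are means over spots, bars are SDs over spots, and dotted lines mark the lowest detected probe of each array (30.9 and 29.5). No E10.5 point exceeds 7.96, and the E11.5 points run from 35.6 to 284.

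The let-7 family, whose mature forms accumulate as embryonic tissues differentiate, had the highest median among the lists measured at both stages, which leaves out the myogenic list. All 6 measured members were higher at E11.5, with a median log2 difference of 1.88. let-7d differed by 2.70 ± 0.044, let-7c by 1.93 ± 0.031, let-7g by 1.90 ± 0.045, let-7f by 1.86 ± 0.029, let-7a by 1.82 ± 0.018 and let-7e by 0.85 ± 0.011. let-7d lay near the detection limit at E10.5 (intensity 32.0), and with normexp it was at 1.45, below let-7f (1.63) and let-7a (1.55), with let-7c at 1.23 and let-7g at 1.14. let-7i was detected at E11.5 only, at least 6.20-fold higher (a log2 bound of 2.63, and 1.38 with normexp). let-7b and miR-98 were also detected at E11.5 only, with no bound above 1. Among the 137 miRNAs detected at both stages, 5 were at least 2-fold higher at E11.5, all of them let-7 members. That no others passed rests on the scaling: outside let-7, 82 passed with no scaling, 74 with the 75th percentile of all probes and 37 with control probes. Fewer passed under some other alternatives: 3 with the gene detection flag, among them miR-503, and 3 with the value table, among them miR-99a and miR-218. With the total gene signal, and with no filter and a floor, 1 each passed. The family's median lay at percentile 100 of 10000 random lists matched on brightness, and its direction was the same under every scaling tried.

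The next largest positive differences were smaller than 2-fold as reported. They were miR-99a (0.81 ± 0.029, 1.21 with the value table and 0.31 with normexp), which shares a transcript with let-7c, miR-23b (0.74 ± 0.019) and its neighbour miR-27b (0.61 ± 0.027), miR-503 (0.62 ± 0.054, from -0.155 with no filter and a floor and 0.063 with normexp to 0.94 with the value table and 1.07 with the gene detection flag), miR-376a (0.64 ± 0.033, and 0.21 with normexp) and miR-127 (0.61 ± 0.025). In the miR-125 and miR-99 families, 3 of 5 measured members were higher, with a median of 0.34 (percentile 83.4), from -0.29 for miR-99b (1.03 with no scaling) to 0.81 for miR-99a. This median was -0.10 with normexp background correction.

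miRNAs at least 2-fold lower at E11.5 relative to the other miRNAs numbered 19. Their 2-fold size, and the direction of 6 of them, rest on the scaling: before scaling, 13 of the 19 were dimmer at E11.5 and 6 were brighter, with unscaled log2 differences from -0.28 (miR-200c) to 0.22, and with no scaling, or with scaling to the 75th percentile of all probes or to control probes, 0 miRNAs were 2-fold lower. The size also depended on other choices, and 14 of the 19 kept it with normexp and 16 with the gene detection flag and with the value table. Of the 19, 5 belonged to the Mir17 cluster and its paralogs, a group that promotes progenitor proliferation. All 11 measured members of that list were lower, with a median of -0.86 (percentile 0.07), a median that was 0.45 with no scaling and 0.35 with the 75th percentile of all probes. The lowest were miR-20b at -1.44 ± 0.012 (X chromosome, mm9, 50095305 to 50095323) and miR-17 at -1.44 ± 0.10, whose probe target also matches a site on the X chromosome. The miR-17 value rests on 1 probe near the detection limit (39.5 at E10.5 and 36.3 at E11.5). With the gene detection flag miR-17 was at -0.66, under 2-fold. miR-106b was least apart, at -0.43 ± 0.017, and at 0.89 with no scaling, 0.79 with the 75th percentile of all probes and 0.33 with control probes. In the miR-15 and miR-16 family, 3 of 4 were lower, with a median of -0.78 (percentile 3.03; 0.54 with no scaling and 0.44 with the 75th percentile of all probes), from -0.84 for miR-15b to 0.18 for miR-322.

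Among the lists with a median, the epithelial miRNAs had the lowest, -1.37 (percentile 0.14), and all 4 measured members were lower at E11.5. miR-200c was at -1.59 ± 0.034, miR-200b at -1.46 ± 0.027 and miR-205 at -0.85 ± 0.018. The list's median stayed below 0 under every scaling, at -0.06 with none, but miR-205 was at 0.46 with no scaling and 0.36 with the 75th percentile of all probes. miR-203 was detected at E11.5 only, with no bound above 1. The sensory epithelium cluster of miR-183, miR-96 and miR-182 had a median of -1.33 (percentile 3.17). With the brightest probe its median was below that of the epithelial list, at -1.36 against -1.32. miR-182 was at -1.48 ± 0.071, miR-183 at -1.33 ± 0.038 and miR-96 at -1.14 ± 0.032, and miR-96 was at 0.18 with no scaling and -0.98 with normexp.

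**Figure D2:**
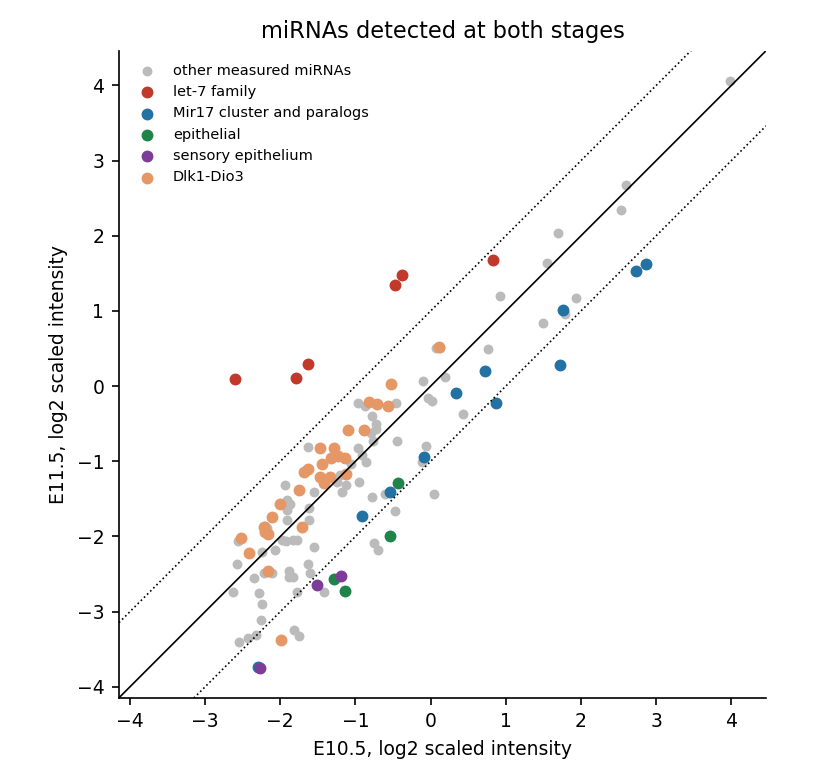
Each point is 1 of the 137 miRNAs detected at both stages, with its log2 scaled intensity at E10.5 (horizontal axis) and E11.5 (vertical axis), coloured by list. The solid line marks equality and the dotted lines 2-fold. Of these 137, the 5 let-7 points above the upper dotted line are the only ones at least 2-fold higher as scaled, and 19 lie below the lower one. With no scaling, 0 would lie below it and 88 would be at least 2-fold higher, 82 of them outside let-7.

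The imprinted Dlk1-Dio3 miRNAs, expressed from the maternal allele of a cluster on chromosome 12, were the largest list. Of 31 measured members, 27 were higher at E11.5, with a median of 0.35 (percentile 99.98), and 4 were lower. A further 13 were detected at E11.5 only, of which 3 had a bound above 1-fold. miR-376a was highest at 0.64, and miR-494 was lowest at -1.39 ± 0.061 (-0.78 with the value table). With normexp background correction this median was -0.06, where the median over all miRNAs was -0.28.

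Other miRNAs at least 2-fold lower belonged to no list. Those named by rule were miR-335-3p (-1.57 ± 0.049), within the imprinted gene Mest, miR-1949 (-1.48 ± 0.034), miR-3096b-3p (-1.47 ± 0.018), miR-574-5p (-1.43 ± 0.064) and miR-466i-5p (-1.34 ± 0.022). The other arm of the same precursor, miR-335-5p, was at -0.15.

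Of the miRNAs detected at one stage only, 62 were detected at E11.5 and 7 at E10.5, with 1 viral miRNA in each count. Of the 62, 9 had a bound above 1-fold and 2, let-7i and miR-206, had one of at least 2-fold, while all 7 at E10.5 had bounds of at least 2-fold. This contrast turned with the scaling: without it, 60 of the 62 and all 7 at E10.5 had bounds above 1-fold, while 13 and 0 had bounds of at least 2-fold. The lowest detected probes lay at 0.160 (E10.5) and 0.0612 (E11.5) after scaling. A miRNA just detected at E10.5, and under the limit at E11.5, thus has a scaled bound above 2-fold by construction. The 2-fold size of the bounds at E10.5 therefore shows nothing beyond detection. miR-206 was under 2-fold with normexp and with detection by every spot (log2 bounds of 0.35 and 0.84). miR-181a was at least 1.52-fold higher at E11.5, with no bound above 1 under normexp and a log2 bound of 0.096 with detection by every spot. The 5 largest bounds at E10.5 were those of the viral mghv-miR-M1-2-3p (at least 4.22-fold, and 1.70-fold without scaling), miR-702 (at least 3.40-fold higher at E10.5), miR-129-1-3p (3.37), miR-715 (3.20) and miR-3085-3p (2.77). Their intensities were close to the detection limit, and without scaling the last 4 bounds were 1.37, 1.35, 1.29 and 1.11.

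The other lists with a median differed little as scaled, and those without one had at most 1 miRNA measured at both stages. With no scaling the medians were 1.39 for the mesenchymal list, 1.49 for the myoblast-linked list, 1.23 for cartilage and 1.28 for miR-30. The mesenchymal and smooth muscle list had 5 measured members, all higher, with a median of 0.08 (percentile 53.1), from miR-21 at 0.05 to miR-199a-5p at 0.28. That median was -0.0204 with the total gene signal and -0.0455 with detection by every spot, and miR-21 was below 0 in both, with the value table and with normexp (-0.11). The miRNAs linked to myoblast differentiation in other tissues had a median of 0.18 (percentile 70.9), with 9 of 11 higher, from miR-181b at -0.33 to miR-503 at 0.62, the latter with the range given above. The cartilage list had a median of -0.08 (percentile 63.2), from miR-455 at -0.27 to miR-140* at 0.13, and the miR-30 family one of -0.03 (percentile 60.1), from miR-30d at -0.66 (-1.23 with detection by every spot and -0.21 with the brightest probe) to miR-30e at 0.33. The cartilage and miR-30 medians were above 0 with no scaling, with the 75th percentile of all probes, with control probes, with quantile normalization and without the dimmest miRNAs, as were, under the first 3 of these, miR-181b, miR-455 and miR-30d. The miR-30 median was also above 0 with the median scaling (0.02), the gene detection flag (0.07) and the value table (0.04). The cartilage and miR-30 medians were further below 0 with normexp (-0.44 and -0.26) and with no filter and a floor (-0.63 and -0.53). Endothelial miR-126-3p was at -0.81 ± 0.012, erythroid miR-451 at -0.60 ± 0.033 and neural miR-218 at 0.50 ± 0.063; without scaling, all 3 were brighter at E11.5, and miR-218 was at -0.23 with normexp and 1.25 with the value table. miR-140* and miR-30e were at -0.27 and -0.23 with normexp and at -0.63 and -0.51 with no filter and a floor. Of the leukocyte miRNAs, 1, miR-223, was detected at E11.5, with no bound above 1 as scaled and one of 1.19-fold without scaling. No pluripotency, Hox cluster, miR-29, miR-34 and miR-449, or Sfmbt2 intron miRNA was detected at either stage.

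**Figure D3:**
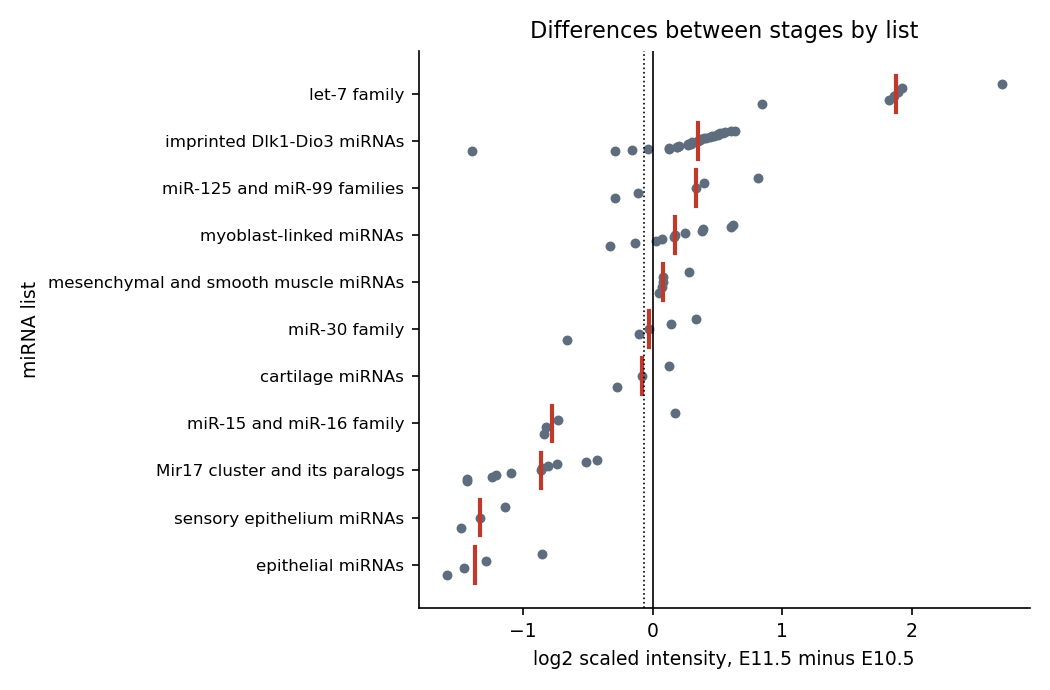
Log2 difference (E11.5 minus E10.5, scaled intensity; horizontal axis) of each measured miRNA, by list. Red bars are list medians, the solid line is 0 and the dotted line is the median over all 137 miRNAs (-0.07). List medians run from -1.37 for epithelial miRNAs to 1.88 for let-7; with no scaling every point moves right by 1.31, which puts the Mir17 median at 0.45.

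miRNAs listed in one co-transcribed cluster differed between the stages by similar amounts. Over 12 clusters with 57 measured members, the mean SD within a cluster was 0.29, against a median of 0.63 for random reassignments matched on brightness, of which 1 of 10000 was as low. The largest spreads were in the clusters that hold a let-7 member, 0.79 for miR-99a with let-7c and 0.61 for miR-99b, let-7e and miR-125a. The let-7c probe target matches 2 sites, beside miR-99a on chromosome 16 and on chromosome 15. Those of miR-17 and miR-199a-5p also match 2 sites each, so their values can hold signal from outside the cluster. Whether probes of similar sequence read each other's miRNAs was not tested. Across 11 precursors with both arms measured, 8 pairs differed in the same direction, with a median absolute difference between arms of 0.21 against 0.67 for random pairs. Across these precursors, which are not independent replicates, Pearson's r was 0.60 and Spearman's rho 0.73.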

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

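Of the tests in this part, those that take out a trend on probe GC content for the let-7 and epithelial lists were set before their values were seen. The tests of the control probes, of let-7e, of the let-7 partners and of miR-205 were chosen only after the result was seen. For differences between single miRNAs, 3 spreads were tried after the values were seen: the spot SE, and the mean (0.21) and the largest (0.40) SD within clusters of one transcript without let-7. A difference was beyond a spread where it exceeded a limit of 2 times that spread, taken over both sides of the difference. The limits from the largest SD were 0.88 for let-7e, 1.13 for the let-7 partners and 0.92 for miR-205. A reading is drawn below only where all 3 give it, under each alternative for let-7e.

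Probes with no expected target in the embryos, and control probes, carried signal. The probes of a viral miRNA, mghv-miR-M1-2-3p, averaged 50.5 at E10.5, and 1 probe of another, mcmv-miR-m01-2, reached 36.0 at E11.5, above the negative controls. The 20 control probes detected on both arrays were brighter at E11.5 by a median of 1.41-fold.

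The E11.5 array was brighter over the detected miRNA probes, by a median log2 ratio of 1.20, and the 2-fold size of the 19 lower miRNAs, and the direction of 6 of them, rest on scaling to it, and for some the size also on the background correction and detection rule. A gain common to the whole array, as the sole cause, would need control probes that are as much brighter. Over the 20 control probes detected on both arrays, the log2 ratio ran from 0.26 to 0.90, with a median of 0.49. These unequal ratios do not fix 1 gain, so a gain as part of the difference stays open. For GC-rich probes, the criterion set beforehand decided nothing, with the sets' GC content at percentiles 62.7 (7 miRNAs in no list) and 52.7 (12 in lists) of random sets, so GC content stays open. Taking out a GC trend was tried afterwards and is not used, since the sets' median GC content was so near that of the other miRNAs that it could move little. Whether miRNAs made up more of the RNA at E11.5, or more RNA was labelled, stays open and was not tested.

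The let-7 family was higher at E11.5 by a median of 1.88. After the GC trend was taken out its median was 1.81, so that trend could not be the whole cause. Reading of 1 let-7 species alone by every let-7 probe would need equal differences. let-7e lay -1.05 from the median of the others, beyond all 3 spreads as reported but within the largest under 4 alternatives. With normexp the gap was -0.56. The gap thus cannot be told apart from ordinary spread, and such reading stays open. Partial reading of 1 member by the probes of others need not give equal differences, so it was not tested and stays open too. A candidate explanation is a release of let-7 precursor processing between the stages, under which let-7 members exceed the partners of their transcripts. let-7c also matches a site on chromosome 15, apart from miR-99a on chromosome 16, so its excess can hold signal not made with miR-99a. The smallest excess was 0.96 (let-7e over miR-125a), beyond the limits from 2 of the 3 spreads but within the largest, 1.13. Against the largest limit of each setting, the smallest excess was beyond it with normexp (0.93 against 0.87) and without the dimmest miRNAs (0.96 against 0.90). It was within it under the other alternatives run, and with the value table (0.61) also within the limit from the mean SD (0.83). A release of processing thus cannot be told apart from ordinary spread within a transcript.

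The epithelial miRNAs were lower by a median of -1.37 relative to other miRNAs, and the GC trend taken out left -1.42. The probe GC content of the 4 members, from 45.4% to 58.1%, lay amid that of the other miRNAs. Taking out the trend could therefore move little, and it decides nothing on GC content here. A smaller share of epithelium in the E11.5 tissue may lower the epithelial miRNAs alike. miR-205 was less low than the mean of miR-200b, miR-200c and miR-429 by 0.59. This was beyond the limits from 2 of the 3 spreads but within the largest, 0.92. A common shift and unequal ones thus cannot be told apart with 1 array per stage. A difference between the stages in epithelial miRNA expression stays open as well.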

How the results depend on the processing

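Of the 15 alternatives, 14 set before the data were examined and 1, scaling to control probes, chosen after seeing the data, 14 were run; scaling to dmr spike-ins was not run, since 0 of 12 such probes were detected. No paired analysis was possible because each stage has 1 array and no result comes from a test; nor could an array be left out. Against the values as reported, scaling moved the median miRNA by 1.22 with the 75th percentile of all probes, 1.31 with no scaling and 0.76 with control probes; normexp moved it by -0.15 and detection by every spot by -0.13. The 75th percentile of all probes was 5.16 and 5.53, below the lowest detected probes (30.9 and 29.5), so it scales on background. miRNAs at least 2-fold higher numbered 80, 88 and 43 under these 3 scalings, against 5, and those lower 0, 0 and 0, against 19. The share of miRNAs higher at E11.5 was 89.1%, 90.5% and 75.9%, against 47.4%, and 27.7% with normexp. The let-7 median was 3.10, 3.19 and 2.64, the epithelial median -0.16, -0.058 and -0.61, and the Mir17 median reversed to 0.35 and 0.45, and was -0.10 with control probes. miR-96 reversed to 0.077 with the 75th percentile of all probes and 0.18 with no scaling. Normexp gave 1.34 for let-7, -0.76 for Mir17 and -1.10 for epithelial miRNAs, and turned the Dlk1-Dio3 median to -0.058; the cause was not tested. Quantile normalization gave an epithelial median of -1.45. With the total gene signal, 35 miRNAs were lower and 19 were detected at E10.5 only, and the let-7, Mir17 and epithelial medians were 1.79, -0.97 and -1.46. Detection by every spot left 2 miRNAs at E10.5 only and 2 of 4 measured arm pairs in one direction, with medians of 1.74, -0.98 and -1.50. The gene detection flag gave 9 higher, 3 of them outside let-7, 19 at E10.5 only, and let-7 and epithelial medians of 1.97 and -1.31; the value table gave 9 higher, 3 outside let-7, and 19 at E10.5 only. Without the dimmest miRNAs, 12 were lower and 2 of 3 measured arm pairs shared a direction, as fewer were measured. With no filter and a floor, 937 were lower, because the scaled floors differ (0.160 and 0.0612), and the let-7 median was 1.80. The 5 let-7 members at least 2-fold higher kept that under 13 of these settings, and 4 did with detection by every spot. The 19 lower miRNAs were all below 0 with control probes, 15 were with the 75th percentile of all probes and 13 with no scaling. Myogenic miRNAs detected at E10.5 were 0 under every alternative run, and at E11.5 they were 4, or 3 with detection by every spot. Scaling, normexp, the brightest probe, the filter on dim miRNAs and the floor leave detection flags unchanged, so they could not alter these counts. Signal over background limits the bounds of miRNAs detected at one stage only.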
